A study of Homo sapiens with 4 samples.

How the data were processed

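Cells of MDA MB 134VI (MM134), an established cell line of invasive lobular breast carcinoma, were deprived of hormone and then given vehicle (0.01% ethanol) or 100 nM estradiol for 24 h, per the labels. Single-cell suspensions were made for 10x Genomics libraries. Per the labels, targeted mRNA libraries cover a commercial pan-cancer gene panel, and separate Haircut libraries read DNA repair. Haircut is a single-cell assay in which synthetic DNA hairpins that carry lesions are exposed to the enzymes of each cell, and processing of a lesion shifts the position at which the strand ends. The labels name 4 samples, 1 library per treatment and assay.

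The deposited matrix holds natural log values, with 1 column per cell, and the deposited annotation gives each cell's treatment, cluster and cell-cycle phase. Counts of UMIs per cell, as the authors deposited them, stand beside the matrix for each of its 3 blocks of rows. One block of 33538 rows carries plain gene symbols, a block of 1253 rows is marked as targeted, and a block of 549 rows is marked as repair, with 9 substrates of 61 positions each. How the plain block was sequenced is not given in the sources used here; it is called the all-gene rows below, and the targeted block the panel rows. The mitochondrial percent per cell was deposited by the authors, and its recomputation from the all-gene rows matched. Per the file headers, the annotation also holds 8 score columns with names built from ER, FOXA1 and MDC1; how the authors made these scores is not given in the sources used here. Cell Ranger 3.0.2, cutadapt 1.8.3, Bowtie2 2.3.2, SAMtools and UMI-tools 0.5.3 and the hg38 build are named, per the submitters' processing notes, with no role or order given.

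The natural log values were turned back into UMI counts. Each deposited value equalled the natural log of 1 plus 10000 times the count over the cell's total in that block; 100% of values above 0 came out whole within 1e-06, and the counts summed to the deposited total in 100% of cells. The design fixed before the data were examined had assumed counts, so the recovered counts were used as planned. Panel genes had 20.9 times as many UMIs in the panel rows as in the all-gene rows, and 97.5% of the gene and cell pairs above 0 in the all-gene rows were also above 0 in the panel rows. No deposited cell was left out. No doublet caller was run; leaving out the 5% of cells with most UMIs in each library was tried instead.

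The vehicle library held 4940 cells and the estradiol library 3367. Summed UMIs were 14080930 and 10352943 in panel rows, 6918198 and 5937422 in all-gene rows, and 4738500 and 4479977 in repair rows, vehicle first. Median UMIs per cell were 2426.5 and 2676 in panel rows, 1199 and 1561 in all-gene rows, and 930 and 1311 in repair rows. Repair UMIs ran as low as 10 per cell in the vehicle library and 13 in the estradiol library. With 1 library per treatment and assay, nothing could be tested between treatments, because cells of 1 library are not replicates. No p-value is given.

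UMIs were summed over the cells of a library and divided by the library's total in that block. Ratios of estradiol to vehicle are given as log2 values or folds with exact 95% intervals (Clopper-Pearson, conditional on the sum of both counts). Shares have exact binomial 95% intervals and library-scaled UMI counts (CPM) exact Poisson 95% intervals. These intervals cover counting error only, not the variation between cultures or preparations. Those of UMI counts treat every UMI as independent. They thus leave out variation between cells as well, also in contrasts of phases within a library. Ratios of all panel genes have a median of -0.09, and a median-of-ratios size factor moves that median to 0.02, so single ratios are read against it.

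Named genes followed a rule fixed before the data were examined. MDC1, ESR1, PGR, PARP1 and PARP2 were always named. The 12 highest and 12 lowest ratios came from genes with at least 200 UMIs, at least 20 CPM in a library and an interval that excluded a ratio of 1. Up to 4 members per list with at least 50 UMIs were taken by size of ratio, and so were every repair substrate with its position of most UMIs and the 3 positions of largest ratio among those with at least 500 UMIs. Some genes that the rule takes are not reported here. The rule was applied to the panel rows and, as an addition chosen after seeing the data, to the all-gene rows. The 20 gene lists covered estrogen-induced and estrogen-repressed genes, S-phase and G2/M genes, base excision repair, ribonucleotide excision, homologous recombination, end joining, mismatch repair, nucleotide excision repair, Fanconi anaemia genes, damage signalling, p53 targets, luminal and lobular genes, immediate-early and stress genes, hypoxia and glycolysis, growth factor signalling, and markers of basal or myoepithelial, mesenchymal, and immune or endothelial cells. A list's median log2 ratio over members with at least 50 UMIs was ranked among 10000 random lists of the same size matched on mean expression, where at least 3 members were measured. Gene coordinates are from the RefSeq annotation of GRCh38, the same build as hg38.

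Repair signal was expressed as a percent of all repair UMIs. After seeing the positions, the sum over positions 44 to 50, where the Normal substrate had few UMIs, was added as a second measure and is called the window. Position numbers and substrate names are those of the deposited row names; their abbreviations are not spelled out in the sources used here. Phases were the authors' calls. They were also called again with scanpy 1.11.5 from the fixed S and G2/M lists, before and after thinning each cell to 800 all-gene UMIs, which left out 951 vehicle and 139 estradiol cells. Spearman's rho between repair windows and enzyme transcripts was taken across the cells of each library. Alternatives are other scalings, equal weight to cells, phases, clusters or bins of depth, leaving out the deepest or shallowest cells, no count minimum and other sets of rows. Other tools were Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.

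The ratio and its interval were tested on simulated data with 200 changed rows per block. For the comparison of panel rows, run on 862 genes, the 95% interval held the simulated ratio for 95.7% of genes and excluded a ratio of 1 on the right side for 100% of the genes simulated at 2-fold or 1.5-fold in either direction. For the all-gene rows, run on 7483 genes, the interval held it for 95.2% and excluded 1 for 92% of genes simulated at 1.5-fold lower, 98% at 2-fold lower and 100% of those simulated higher. For the repair positions, run on 439 rows, the interval held the simulated ratio for 94.8% of rows. These simulated counts were Poisson draws of library sums, so coverage near 95% followed from the construction. Variation between cells was not simulated for the intervals. For phase calls on thinned cells, 97.25% of cells simulated in S and 75.25% of those simulated in G1 were called as such. These cells were drawn from a pooled profile in which only the genes of the calling lists were raised or lowered. The percents therefore do not measure how accurate calls on real cells are.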

Results

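Vehicle-treated and estradiol-treated MM134 cells were profiled for transcripts and for DNA repair signal in the same cells, with 1 library per treatment and assay. MM134 is a line of invasive lobular breast carcinoma, the histological type in which loss of E-cadherin is frequent, and it expresses the estrogen receptor. The title of the series concerns MDC1, an adaptor that binds phosphorylated histone at DNA breaks, and DNA repair in lobular cancer. The comparison asks how 24 h of 100 nM estradiol after hormone deprivation relates to expression and to repair of defined lesions. The vehicle library held 4940 cells and 14080930 panel UMIs, and the estradiol library 3367 cells and 10352943 panel UMIs. There are no replicates, so every difference below describes these libraries and its interval covers counting error only.

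In the panel rows, PGR, PMAIP1 and WNT4 had the highest ratios of estradiol to vehicle among genes that met the count minimum, and TXNIP, PPARGC1A and CXXC4 the lowest. PGR, the progesterone receptor and a classic estrogen receptor target, was at 23.3 CPM with estradiol (95% Poisson interval 20.4 to 26.4) and 8.17 CPM with vehicle (6.74 to 9.80), a 2.85-fold difference (2.27 to 3.59). PMAIP1, which encodes the BH3-only protein NOXA, was 2.51-fold higher (2.33 to 2.71), and WNT4, a secreted Wnt ligand, was 2.35-fold higher (log2 ratio 1.23, 1.14 to 1.32). RASGRP1, a Ras exchange factor, was 2.12-fold higher and the early growth response factor EGR3 2.09-fold higher. Next in order came LAMA3 at a log2 ratio of 0.97, FZD7 at 0.94, ZNF703 at 0.89, JAK2 at 0.88, RET at 0.84, BID at 0.84 and the replication licensing factor CDC6 at 0.72. ZNF703 was by far the most abundant of them, at 5250 CPM with vehicle and 9751 CPM with estradiol.

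At the other end, TXNIP, which binds thioredoxin and limits glucose uptake, was at 2945 CPM with vehicle (2916 to 2973) and 697 CPM with estradiol (681 to 714), 4.22-fold lower (4.12 to 4.33). PPARGC1A, a coactivator of mitochondrial genes, was 3.51-fold lower (2.99 to 4.13), CXXC4 2.89-fold lower, the antiproliferative gene BTG2 2.69-fold lower and the forkhead factor FOXO1 2.65-fold lower. ZBTB20 had a log2 ratio of -1.40, the interleukin 1 receptor gene IL1R1 -1.37, DACH1 -1.27, LAG3 -1.20, PAK3 -1.16, PNRC1 -1.16 and the mTOR inhibitor DDIT4 -1.10. Among the 822 panel genes at the count minimum, 5 were at least 2-fold higher with estradiol and 24 at least 2-fold lower. With a median-of-ratios size factor, which shifts the median panel ratio from -0.09 to 0.02, the split was 8 higher and 11 lower. CCND1, which encodes cyclin D1, took 14.7% of panel UMIs with estradiol and 10.98% with vehicle.

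MDC1 (chromosome 6, 30699807 to 30717281) was at 868 CPM with vehicle (853 to 884) and 838 CPM with estradiol (820 to 856), a log2 ratio of -0.05 that turns to 0.06 with a median-of-ratios size factor and to 0.01 when the 10 most abundant genes leave the total. The estrogen receptor gene ESR1 (chromosome 6, 151656672 to 152129619) was at 3340 and 3322 CPM, a log2 ratio of -0.01 (-0.03 to 0.01). The genes of the ADP-ribose polymerases that PARP inhibitors target were higher with estradiol. PARP1 (chromosome 1, 226360691 to 226408093) was at 5014 against 4039 CPM, 1.24-fold higher (1.23 to 1.26), and PARP2 (chromosome 14, 20343635 to 20357904) at 556.5 against 453 CPM, 1.23-fold higher (1.19 to 1.27). PGR lies on chromosome 11, 101029624 to 101129813.

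The all-gene rows, less deep but not limited to the panel, gave the same direction for 497 of 573 genes measured in both blocks, with a Pearson correlation of 0.93 and a Spearman correlation of 0.92 across genes, which are not independent replicates. Both blocks come from the same cells, so this is no second measurement of the treatment difference. Among genes with at least 200 UMIs and 20 CPM in a library, their highest ratios belonged to PGLYRP2, a peptidoglycan amidase gene, at 40.9 against 5.35 CPM (7.65-fold, 5.40 to 11.1), and to MGP, which encodes matrix Gla protein, at 29.6 against 4.34 CPM (6.84-fold, 4.62 to 10.4). RAPGEFL1 followed at a log2 ratio of 1.92, the imprinted gene PEG3 at 1.91, FMN1 at 1.61, AMZ1 at 1.61, AC124067.4 at 1.41, NOS1AP at 1.40, PKIB at 1.36, the estrogen-regulated growth gene GREB1 at 1.34, NKAIN1 at 1.32 and TFCP2L1 at 1.30. Lowest were ZBTB20 at -2.17, FBXO32, an atrophy-related ubiquitin ligase gene, at -2.14, CXXC4 at -2.11, TXNIP at -1.90, STON1 at -1.81, BTG2 at -1.65, MS4A7 at -1.64, SLIT1 at -1.62, BCAS1 at -1.58, the ion cotransporter gene SLC12A2 at -1.57, IL1R1 at -1.50 and LDLRAD4 at -1.47.

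Known estrogen target genes separated by direction. Of 11 estrogen-induced genes measured in the panel rows, all 11 were above a ratio of 1 and 5 were at least 1.5-fold higher, with PGR, WNT4, EGR3 and RET leading. The list median of 0.44 lay at the 99.98 percentile of matched random lists. In the all-gene rows 22 of 39 measured members were at least 1.5-fold higher and 0 lower, with a median of 0.74 at the 100 percentile. PDZK1, a scaffold protein gene with fewer than 200 UMIs, had the largest ratio of the list there, 8.32-fold at 25.3 against 3.04 CPM, and SLC7A5, an amino acid transporter gene, had a log2 ratio of 1.71. Estrogen-repressed genes stood on the other side: 10 of 11 in the panel rows were at least 1.5-fold lower, with a median of -0.81, and 12 of 17 in the all-gene rows, with a median of -0.83, both at the 0 percentile. ERBB4 (-1.39), IL1R1 (-1.37), PNRC1 (-1.16) and TGFB3 (-1.05) led in the panel rows, and CCNG2 (-1.41), BMF (-1.32) and KLF4 (-1.28) stood beside IL1R1 in the all-gene rows.

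DNA replication genes were higher with estradiol. All 13 measured S-phase genes of the panel were above a ratio of 1, with a median of 0.41 at the 100 percentile and 1 member, CDC6, at least 1.5-fold higher; BLM was at 0.48 and MCM5 at 0.46. In the all-gene rows 11 of 42 were at least 1.5-fold higher, among them DTL (0.83), UHRF1 (0.78), CDC45 (0.78) and EXO1 (0.73), with a median of 0.43. The 7 measured G2/M genes of the panel had a median of -0.17 at the 24.3 percentile, led by CENPA (-0.45), CDC25C (-0.34), TOP2A (-0.27) and AURKA (-0.17), and 0 reached 1.5-fold. The 54 in the all-gene rows had a median of -0.09 at the 0.68 percentile, with AURKB (0.56) and TMPO (0.43) on the higher side and CDC25C (-0.67) and CENPA (-0.53) on the lower. Within the cells called S by the authors, the S-phase median of the panel was -0.03, against 0.45 within G1 cells and 0.22 within G2M cells. The G2/M medians changed sign between phases, at 0.23 (panel) and 0.32 (all-gene rows) within G1 cells, 0.05 and 0.01 within S cells, and -0.23 and -0.22 within G2M cells. Calling phases again from these same lists gave the authors' phase in 88.0% of cells. Cells of a phase are thus largely selected on these genes. The medians of both lists within phases therefore cannot separate a change in phase shares from a change within cells. The G1 cells of the libraries fell in different clusters of the authors. Cluster 1, rich in S cells, held 27.7% of them with estradiol and 5.86% with vehicle, and cluster 2 held 6.02% and 43.2%.

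Repair genes shared part of this direction. The base excision repair list had a panel median of 0.29 over 6 genes (99.2 percentile) with FEN1 at 0.44 and POLB at -0.30, and an all-gene median of 0.22 over 25 genes (99.96 percentile) with the uracil glycosylase gene UNG at 0.57, NTHL1 at 0.55 and NEIL1 at -0.56; 0 members reached 1.5-fold in either block. Homologous recombination genes had medians of 0.18 over 17 panel genes (99.9 percentile) and 0.24 over 24 (100 percentile), with XRCC2 at 0.56 in the panel, RAD54L at 0.43, and RBBP8 at 0.56 and RAD51B at -0.60 (-1.25 to 0.03) in the all-gene rows, where 2 members, XRCC2 (0.80) and EXO1 (0.73), were at least 1.5-fold higher. End joining genes had medians of 0.37 over 5 genes (98.4 percentile) and 0.21 over 13 (98.9 percentile), with POLQ at 0.48, PRKDC at 0.38, MAD2L2 at 0.37 and LIG4 at -0.35 in the panel and 1 member each way past 1.5-fold in the all-gene rows. Without genes that are also in the S-phase and G2/M lists the all-gene medians were 0.12 for base excision repair and 0.19 for homologous recombination, and the panel medians 0.28 and 0.15. For the full lists in the all-gene rows, base excision repair was at 0.27 within G1 cells, 0.06 within S cells and 0.07 within G2M cells, homologous recombination at 0.44, -0.03 and -0.02, and end joining at 0.36, 0.15 and 0.16, with the same difference in clusters between the G1 cells. In the panel, base excision repair was at 0.26, 0.0031 and 0.24, homologous recombination at 0.23, -0.02 and 0.03, and end joining at 0.35, 0.16 and 0.20.

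Where at least 3 members were measured, the remaining repair lists lay within the middle 95% of matched random lists, except damage signalling in the all-gene rows. Mismatch repair had a panel median of 0.05 over 6 genes (85.5 percentile) and 0.17 over 8 all-gene members (95.6 percentile), with MSH6 at 0.40, PMS1 at 0.10 and PMS2 at -0.08 in the panel. The PMS2 ratio turned to 0.03 with a median-of-ratios size factor and to 0.12 in the all-gene rows. Nucleotide excision repair had medians of -0.13 over 8 genes (40.7 percentile) and -0.04 over 14 (43.1 percentile), with ERCC5 at -0.42, XPA at -0.31, ERCC6 at -0.25 and ERCC1 at -0.18. Fanconi anaemia genes had medians of 0.08 over 11 (93.3 percentile) and 0.01 over 13 (72.6 percentile), led in the panel by FANCI (0.32), FANCB (0.30), FANCD2 (0.27) and FANCA (0.22). Damage signalling genes, MDC1 among them, had medians of 0.05 over 9 (88.7 percentile) and 0.21 over 15 (99.5 percentile), with CDC25A at 0.66, WEE1 at -0.37, CHEK1 at 0.32 and CHEK2 at 0.27 in the panel and ATRIP at 0.72 in the all-gene rows. The all-gene damage signalling median was 0.48 within G1 cells, 0.06 within S cells and 0.12 within G2M cells. With equal weight to each phase the panel medians of the mismatch repair, Fanconi anaemia and damage signalling lists were -0.01, -0.04 and -0.00. Ribonucleotide excision had 1 measured panel gene, TOP1 (-0.26); its 6 all-gene members had a median of 0.04 (72.9 percentile), with RNASEH2A, the catalytic subunit gene of RNase H2, 2.04-fold higher (1.60 to 2.60), RNASEH1 at 0.14 and SAMHD1 at -0.28.

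Among the other lists, luminal and lobular genes lay below the middle 95% of matched random lists in both blocks and p53 targets in the all-gene rows alone. The p53 target list split: BTG2 (-1.43), CDKN1A (-0.64) and GADD45A (-0.57) were lower and PMAIP1 (1.33) higher in the panel, and BBC3 was at -1.18 and BAX at 0.77 in the all-gene rows. Its medians were -0.31 over 8 genes (4.95 percentile) and -0.33 over 14 (0.25 percentile), with 1 panel member at least 1.5-fold higher and 2 lower, and 2 each way in the all-gene rows. Luminal and lobular genes had medians of -0.34 over 11 (0.58 percentile) and -0.25 over 17 (0.01 percentile), with 1 panel member at least 1.5-fold higher and 1 lower and 2 higher and 1 lower in the all-gene rows. ID1 (-0.56) and ID2 (-0.81) were lower and WNT4 was higher, while in the all-gene rows the keratin gene KRT8 was at 0.84 and CTNND1, which encodes p120 catenin, at -0.57. Immediate-early and stress genes had medians of -0.17 over 5 (29.1 percentile) and -0.10 over 15 (12.9 percentile), with 2 panel members at least 1.5-fold lower and 5 all-gene members lower against 1 higher. Examples are FOS (-1.05), JUN (-0.63), HSPA1A (0.34, which shares near-identical sequence with HSPA1B) and DDIT3 (-0.17) in the panel and DUSP1 (-1.40), ATF3 (-1.32) and the chaperone gene HSPA5 (0.85) in the all-gene rows.

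Growth factor signalling genes had medians of -0.15 over 26 (21.7 percentile) and -0.12 over 21 (6.36 percentile). DUSP6 (-1.08), a phosphatase induced by ERK signalling, and the receptor genes ERBB3 (-0.99) and ERBB4 (-1.39) were lower and FGFR3 (0.93) higher, and 5 panel members were at least 1.5-fold lower and 1 higher. In the all-gene rows FGFR4 was at -0.71 and ERBB2 at -0.66. Hypoxia and glycolysis genes had a panel median of -0.22 over 3 (28.1 percentile), with VEGFA at -0.43, PDK1 at -0.22 and BNIP3 at -0.03, and an all-gene median of 0.04 over 8 (62.4 percentile), with ENO1 at 0.64 and LDHA at 0.33. Of markers of other cell types, the immune or endothelial list had 0 measured members in either block and the basal or myoepithelial list 1, OXTR (0.26). The mesenchymal list had 2 in the panel, COL1A1 (-0.49) and FN1 (-0.22), and 5 in the all-gene rows with a median of -0.31 (5.70 percentile), among them TWIST1 (-0.61), VIM (-0.41) and ZEB1 (-0.18).

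**Figure D1:**
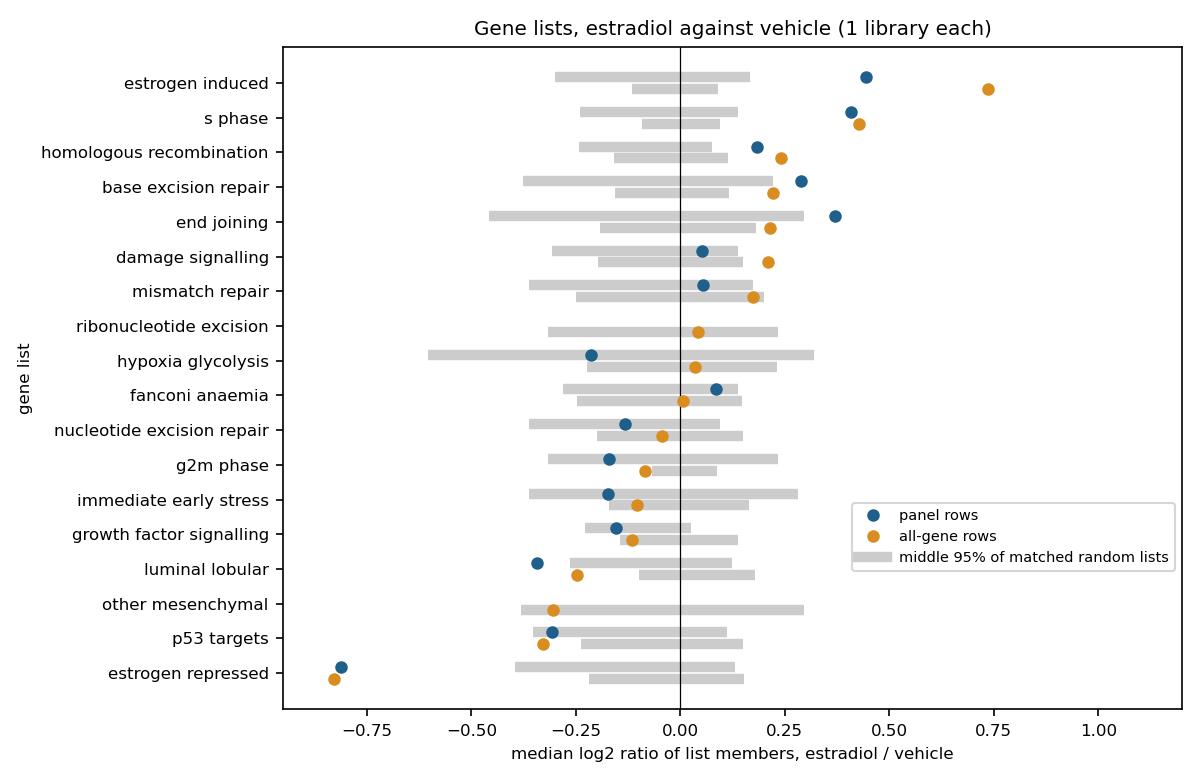
Median log2 ratio of estradiol to vehicle for each gene list with at least 3 measured genes, in panel rows and all-gene rows; grey bars span the middle 95% of 10000 matched random lists. Estrogen-induced genes (0.44 and 0.74) and S-phase genes (0.41 and 0.43) lie above their bars and estrogen-repressed genes (-0.81 and -0.83) below.

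More cells were called S in the estradiol library. By the authors' phases, 977 of 3367 estradiol cells were in S, 29.0% (exact binomial interval 27.5 to 30.6), against 773 of 4940 vehicle cells, 15.6% (14.6 to 16.7). G1 cells made up 34.5% (32.9 to 36.2) with estradiol and 50.5% (49.1 to 51.9) with vehicle, and G2M cells 36.4% (34.8 to 38.1) and 33.9% (32.6 to 35.2). Phase calls depend on depth, and the estradiol cells were deeper. After thinning to 800 UMIs and calling phases again, S cells were 30.6% with estradiol (29.1 to 32.3) and 20.3% with vehicle (19.1 to 21.6), and G1 cells 22.1% and 33.6%. The order of the G2M shares turned when only cells of at least 800 all-gene UMIs were kept, to 37.2% with estradiol and 39.3% with vehicle by the authors' phases.

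Repair signal in each library was described per substrate. The Normal substrate, taken here as the control, had most UMIs at position 20, and its window of positions 44 to 50 held 0.113% of its UMIs with vehicle and 0.102% with estradiol. The Abasic substrate had its main position at 46, which alone took 3.09% of all repair UMIs with vehicle (3.07 to 3.10) and 2.60% with estradiol (2.58 to 2.61); its window held 63.8% and 57.9% of its own UMIs. Uracil1 peaked at position 45, with 1.47% of repair UMIs in either library and 27.4% and 28.0% of its own UMIs in the window. In the window Uracil2 held 15.3% and 15.4% of its UMIs, Uracil3 10.2% and 11.5%, GU 7.21% and 8.48%, and riboG 6.13% and 5.997%, each with position 45 as the highest of its window. CI and TI had 0.134% and 0.253% of their UMIs in the window with vehicle. Their main positions had low numbers, 9 for CI with 6.18% of repair UMIs with vehicle and 6 for TI with 4.90%, and those of GU (position 6, 2.84%), riboG (9, 1.27%), Uracil2 (20, 1.35%), Uracil3 (20, 0.127%) and Normal (20, 3.23%) lay outside the window as well; with estradiol, position 15 was the highest of GU. An Abasic window UMI was seen in 99.98% of vehicle cells and a Uracil1 window UMI in 99.8%, against 13.7% for Normal; the median vehicle cell had 39 Abasic and 19 Uracil1 window UMIs.

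**Figure D2:**
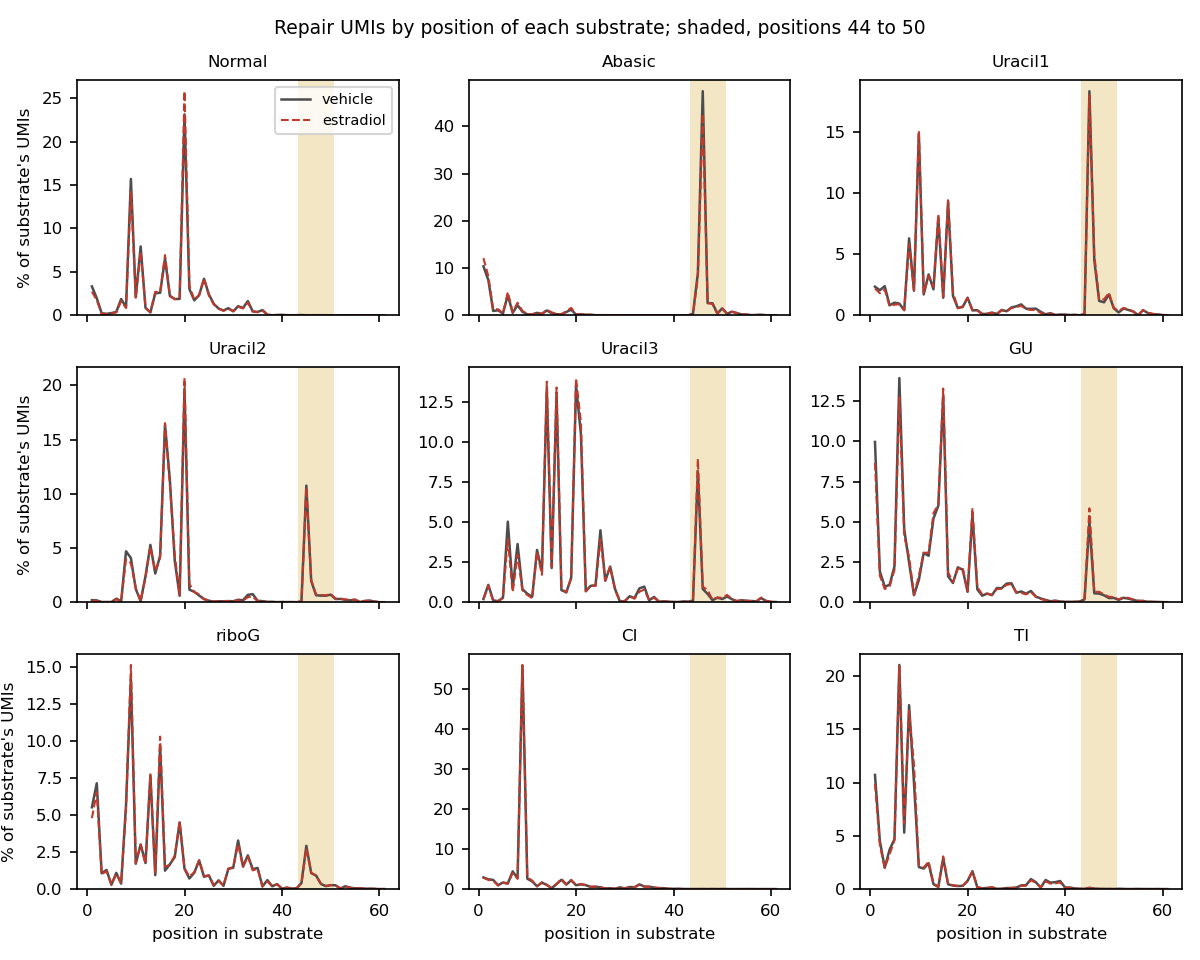
UMIs at each position as a percent of the substrate's UMIs, for the 9 substrates, in the vehicle library (solid) and the estradiol library (dashed). The shaded positions 44 to 50 hold a peak in Abasic, Uracil1, Uracil2, Uracil3, GU and riboG and at most 0.253% of the UMIs of Normal, CI and TI.

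Between treatments, the Abasic peak was lower and the GU window higher with estradiol as a share of repair UMIs, although the GU window turned to -0.0096 with equal weight to each of the authors' clusters. Abasic position 46 had a log2 ratio of -0.25 (-0.26 to -0.24) and the Abasic window -0.24 (-0.25 to -0.23), while Abasic positions outside the window were at 0.12. The small windows of Normal (-0.16, -0.31 to -0.0008), CI (-0.20, -0.36 to -0.04) and TI (-0.21, -0.29 to -0.13) were lower too. A lower window was thus not particular to Abasic. The GU window was at 1.67% with estradiol and 1.47% with vehicle, a log2 ratio of 0.18 (0.17 to 0.20), and the Uracil3 window at 0.24 (0.18 to 0.30). Uracil1 position 45 did not differ detectably at this depth, at 0.00 (-0.01 to 0.02); the Uracil1 window was at 0.06, the Uracil2 window at 0.09 and the riboG window at -0.04 (-0.07 to -0.02), which ran from -0.36 to 0.52 over bins of repair UMIs per cell and turned to 0.43 in UMIs per cell. The main positions of the others were at 0.15 for Normal, 0.15 for Uracil2, 0.12 for Uracil3, -0.18 for GU, 0.08 for riboG, -0.00 for CI and 0.04 for TI. The 3 largest ratios among positions with at least 500 UMIs were 0.61 each, at Uracil2 position 21, Uracil1 position 51 and Uracil3 position 47. Estradiol cells had more repair UMIs of every substrate: per cell and without scaling, Abasic position 46 was higher by 0.22 and Normal position 20 by 0.62. Over 5 bins of repair UMIs per cell, the Abasic position averaged -0.09, Uracil1 position 45 0.23 and the GU window 0.37. With equal weight to each cluster the Abasic window was at -0.14, the Uracil1, Uracil2 and Uracil3 windows turned to -0.06, -0.04 and -0.01, and the riboG window was at -0.15. As a share, the pooled riboG window ratio joined opposite directions, at 0.14 (0.10 to 0.19) within G1 cells, 0.03 (-0.03 to 0.09) within S cells and -0.24 (-0.27 to -0.20) within G2M cells. In UMIs per cell the riboG window was higher with estradiol in each phase.

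Uracil repair signal was highest in S phase in both libraries. Of all repair UMIs in vehicle cells, the Uracil1 window took 2.07% in G1, 2.80% in S and 2.10% in G2M, and in estradiol cells 2.13%, 2.75% and 2.11%. The S to G1 log2 ratio was 0.44 (0.41 to 0.46) with vehicle and 0.37 (0.34 to 0.39) with estradiol for Uracil1, 0.47 and 0.37 for Uracil2, 0.88 and 0.72 for Uracil3, and 0.56 and 0.49 for GU. Positions of Uracil1 outside the window were at -0.06 and -0.07. The Abasic window ran the other way, from 4.57% in G1 to 4.15% in S and 3.66% in G2M with vehicle and from 3.86% to 3.58% and 3.22% with estradiol, a G2M to G1 log2 ratio of -0.32 and -0.26; in UMIs per cell these ratios were 0.02 and 0.02. The riboG window was highest in G2M, at 0.682% against 0.458% in G1 with vehicle (log2 ratio 0.57, 0.54 to 0.61) and 0.580% against 0.506% with estradiol (0.20, 0.15 to 0.24). Over bins of repair UMIs per cell this riboG ratio ran from -0.07 to 1.00 with vehicle and from -0.06 to 0.91 with estradiol, so its direction was not the same in every bin. In the Normal substrate the S to G1 ratio of the window was 0.30 (-0.01 to 0.60) with vehicle and -0.14 (-0.45 to 0.17) with estradiol. Its G2M to G1 ratio was 0.33 (0.10 to 0.56) and 0.17 (-0.10 to 0.44), and the wide interval with estradiol held the riboG ratio. The CI interval with estradiol held it too (0.04, -0.24 to 0.32), but that of TI lay below it (-0.0045, -0.15 to 0.14). With vehicle, the S to G1 interval of the control also held the ratios of Uracil1, Uracil2 and GU, but not that of Uracil3. With estradiol it lay below all 4. CI and TI, which also had few window UMIs, had S to G1 intervals below all 4 in both libraries. With vehicle these were 0.06 (-0.26 to 0.37) for CI and -0.12 (-0.28 to 0.04) for TI. With estradiol they were -0.12 (-0.44 to 0.19) and 0.04 (-0.12 to 0.19).

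**Figure D3:**
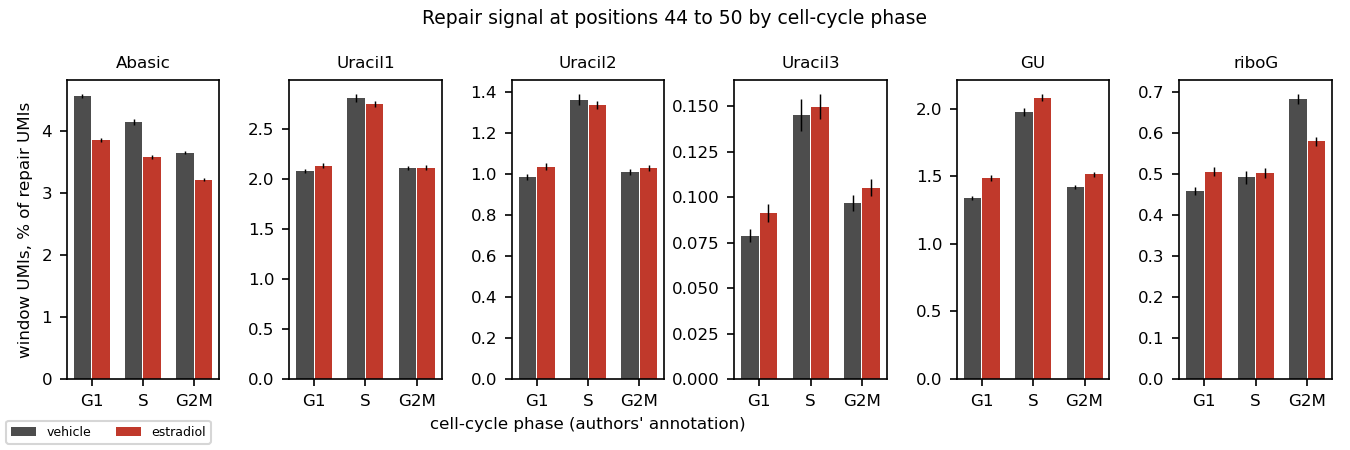
UMIs at positions 44 to 50 as a percent of all repair UMIs of the cells in each phase (authors' annotation), for 6 substrates in vehicle and estradiol cells; error bars are exact binomial 95% intervals for counting error only. Uracil1, Uracil2, Uracil3 and GU are highest in S, Abasic is highest in G1 and riboG in G2M, in both libraries.

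Transcripts of the matching enzymes were weakly related to the windows across cells. Spearman's rho between the Uracil1 window share and UNG was 0.08 with vehicle and 0.07 with estradiol, with UNG UMIs in 3.77% and 6.71% of cells. Within phases it was 0.03 in G1, 0.07 in S and 0.03 in G2M with vehicle, and 0.06, 0.0058 and -0.02 with estradiol. For Uracil2 it was 0.07 and 0.09 and for Uracil3 0.09 and 0.09. The UNG transcript itself was at 79.1 CPM in S cells (63.1 to 97.9) against 19.3 in G1 cells (14.7 to 24.97) with vehicle, and at 85.2 (71.8 to 100.5) against 31.2 (23.7 to 40.4) with estradiol. UNG is itself in the S-phase list, and with phases called again without it the levels were 58.6 in S and 19.3 in G1 with vehicle and 73.1 and 29.7 with estradiol. The riboG window had a rho of 0.06 and 0.05 with RNASEH2A, 0.06 and 0.01 with RNASEH2B, and 0.05 and 0.01 with RNASEH2C. The Abasic window had a rho of -0.08 and -0.04 with APEX1, the main abasic endonuclease gene, and this sign turned in raw UMIs, where it was 0.03 and 0.03. No substrate name spells out hypoxanthine or oxoguanine, so MPG and OGG1 were not paired. Most cells had no UMI of these enzymes, which limits each rho.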

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

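The per-cell scores deposited with the annotation enter no comparison of the report, and 6 of the 8 had a higher mean in estradiol cells than in vehicle cells; all tests in this part were chosen after the scores were seen. The score named ER alone was higher by 0.0115, ER with MDC1 by 0.00721, ER with FOXA1 by 0.0105 and ER with FOXA1 and MDC1 by 0.0165. Of those named as targeted, ER with FOXA1 was higher by 0.0291 and ER with FOXA1 and MDC1 by 0.00331, while ER alone differed by -0.00639 and ER with MDC1 by -0.0285. The standard deviation over vehicle cells was 0.0152 for ER alone and 0.0593 for the targeted score of ER with MDC1. Averaged over bins of equal UMIs per cell, the difference was 0.00508 for ER alone, 0.000758 for ER with MDC1 and -0.00706 for the targeted score of ER with FOXA1 and MDC1, so 5 of the 8 were then above 0. What the scores measure is not given in the sources used here, and no explanation was tested.

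None of the 36 contrasts of S or G2M with G1 compared, over substrates inside and outside the window, had opposite directions in the vehicle and estradiol libraries with both counting intervals excluding a ratio of 1. These contrasts do not compare the treatments within a phase. Between treatments, the share of the riboG window was at 0.14 (0.10 to 0.19) within G1 cells and -0.24 (-0.27 to -0.20) within G2M cells. In UMIs per cell the riboG window was higher with estradiol in both, at 6.10 against 3.97 in G1 and 8.50 against 7.49 in G2M. Its share ratio also ran from 0.52 in the lowest bin of repair UMIs per cell to -0.36 in the highest. The share of the Uracil1 window was at 0.04 (0.02 to 0.06) within G1 cells and -0.03 (-0.05 to -0.01) within S cells. The cause was not tested.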

How the results depend on the processing

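Alternatives on all-gene rows, cells of 2000 to 3500 panel UMIs, the window, equal weight to depth bins, equal weight to each phase or cluster for repair, phases called without UNG, cells of at least 800 UMIs and calls without thinning were added after the data were seen; the others were fixed before the data were examined. Except where a value or the construction of the alternative shows it, the cause was not tested. No paired analysis was possible because each group has 1 library. Leaving out cells under 500 panel UMIs removed no cell. Scaling by UMIs per cell or by the Normal substrate divides all substrates of 1 library by 1 number, so it was not run for shares within a library. Low repair depth, down to 10 UMIs in a cell, limits shares per cell.

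A median-of-ratios size factor gave list medians of 0.56 (estrogen-induced), -0.70 (estrogen-repressed), 0.52 (S-phase) and -0.0596 (G2/M), 8 genes at least 2-fold higher and 11 lower, and turned MDC1 to 0.0590 and PMS2 to 0.0344; it subtracts 1 number from every ratio. Without the 10 most abundant genes in the total, the medians were -0.75 (estrogen-repressed), 0.47 (S-phase) and -0.11 (G2/M), 14 genes were at least 2-fold lower and MDC1 was at 0.0113. All-gene rows gave 0.74 (estrogen-induced) and -0.0854 (G2/M), and turned PMS2 to 0.12 and the hypoxia list to 0.0360. Mean CPM per cell gave 0.45 (S-phase) and -0.0527 (G2/M), and leaving out the deepest cells -0.0938 (G2/M). Cells of 2000 to 3500 panel UMIs gave 0.53 (estrogen-induced) and -0.31 (G2/M).

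With equal weight to each phase the S-phase median was 0.13, the damage signalling, Fanconi anaemia and mismatch repair medians turned to -0.00351, -0.0379 and -0.0117, and the Abasic position was at -0.23, the Uracil1 position at -0.0412 and the GU window at 0.10. With equal weight to each of the authors' clusters the Abasic position was at -0.13, the Uracil1 position at -0.0446 and the riboG window at -0.15, and the GU, Uracil1, Uracil2 and Uracil3 windows turned to -0.00958, -0.0618, -0.0424 and -0.0143. In UMIs per cell the Abasic position turned to 0.22, the Abasic window to 0.24, the GU position to 0.29 and the riboG window to 0.43, and the Uracil1 position (0.48) and GU window (0.65) moved up, since estradiol cells had more repair UMIs. In the same unit the G2M to G1 ratios of the Abasic window turned to 0.0186 (vehicle) and 0.0177 (estradiol) and the S to G1 ratios of Uracil1 were 0.59 and 0.48. Equal weight to depth bins gave -0.0871 (Abasic position), 0.23 (Uracil1 position) and 0.37 (GU window), and turned the GU position to 0.0116, Normal to -0.0145, Uracil3 to -0.11 and riboG to -0.0321; by phase it gave -0.20 and -0.19 (Abasic, G2M to G1) and 0.45 (Uracil1, S to G1, estradiol).

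Summed over all positions, the ratios were -0.0951 (Abasic) and 0.0320 (Uracil1), Normal and riboG turned to -0.00918 and -0.0118, and the shares within a library were 6.51% and 6.09% (Abasic) and 8.02% and 8.20% (Uracil1). Cells with at least 500 repair UMIs gave 0.20 (GU window), 0.0206 (Uracil1 position) and a Uracil1 share of 1.44% with vehicle. Means of per-cell shares gave 0.21 (GU window), turned the riboG window to 0.00721, and put the Abasic share at 3.23% and 2.71% and the Uracil1 share at 1.56% and 1.57%. Without the deepest cells these shares were 3.16%, 2.66%, 1.496% and 1.5005%.

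Phases called again on thinned cells gave an S difference of 10.3 points, Abasic G2M to G1 ratios of -0.29 and -0.24 and a Uracil1 S to G1 ratio of 0.34 with vehicle. The G2M difference turned to -2.10 points (authors' phases) and -0.118 points (called again) in cells of at least 800 UMIs. The rho of Abasic and APEX1 turned to 0.0292 and 0.0284 in raw UMIs and to 0.0365 and 0.0331 in cells of middle depth. Of 632 values for 79 named genes 274 moved beyond their interval and 4 turned, of 144 values for 16 list medians 56 and 4, of 129 for 15 repair ratios 56 and 15, of 24 for 8 windows by phase 17 and 2, of 32 for 16 rho 2 and 4, of 15 for 3 phase shares 4 and 2, of 72 for 18 shares within a library 55 and 0, and of 14 for 2 counts of genes 3 and 0.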

Other observations

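The tests in this part on shares of phases and of clusters, on recovery of the Abasic or uracil substrate as a whole and on library preparation were chosen after the values were seen, as were the values by cluster, the calls without UNG, the regions and correlations between substrates. HSPA5, the main chaperone of the endoplasmic reticulum, had a log2 ratio of estradiol to vehicle of 0.85 (0.72 to 0.98) in the all-gene rows. A hypothesis that unfolded protein response genes move as a set was tested on 15 other members that had not been looked at. Their median log2 ratio was 0.33, above the value that 95% of matched random lists stayed under (0.13). Of the 15, 12 were above 0 and 3 at least 1.5-fold higher, with HYOU1 at 1.02, SDF2L1 at 0.81, PDIA3 at 0.65 and PDIA6 at 0.53. HERPUD1 (-0.57) and SEL1L (-0.19), of the degradation pathway of that compartment, and DNAJB9 (-0.46) were lower, and the intervals of DNAJC3 (0.14, -0.10 to 0.38) and SEC61B (0.08, -0.03 to 0.19) included 0.

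Window shares of the uracil substrates and riboG had positive correlations across the cells of each library. Across vehicle cells the rho between window shares was 0.66 for Uracil1 and GU and 0.63 for Uracil1 and Uracil2, with 0.71 and 0.67 across estradiol cells, and it was lower for Uracil1 and Uracil3, at 0.36 and 0.42. The riboG window had a positive rho with each uracil substrate as well, from 0.21 with Uracil3 to 0.33 with GU across vehicle cells and from 0.20 with Uracil1 to 0.29 with GU across estradiol cells. Positive values are thus not particular to uracil. Abasic and riboG windows had a negative rho of -0.28 and -0.16. By the authors' clusters, the Uracil1 window was highest in cluster 1, at 2.94% of repair UMIs in vehicle cells and 2.68% in estradiol cells, and 69.8% and 60.3% of that cluster's cells were in S. It was lowest in cluster 7, at 1.56% and 1.47%. On chromosome 8 between 37000000 and 43000000, 4 of the 20 most abundant panel genes lie together, and on chromosome 11 between 69000000 and 79000000 another 3. These regions took 6.70% and 13.2% of panel UMIs with vehicle and 6.86% and 16.9% with estradiol. In the panel rows ZNF703 (0.89) and CCND1 (0.42) led them, while their median ratios were -0.09 and 0.02. In the all-gene rows ZNF703 (1.03) and STARD10 (0.77) led them, with medians of -0.08 and 0.03.

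As a share of repair UMIs, the Abasic window was lower with estradiol by a log2 ratio of -0.24. In UMIs per cell the Abasic window was higher, by 0.24, so the difference weighed here is one of share only. The shares of the Normal (-0.16), CI (-0.20) and TI (-0.21) windows, which hold few UMIs, were lower too, and their intervals held -0.24. Those of the Uracil1, Uracil2, Uracil3 and GU windows were higher. The fall in share is thus not particular to the Abasic substrate. The shares of the called phases are argued against as the whole cause of the Abasic difference, since equal weight to each phase left -0.21. A lower recovery of the Abasic substrate as a whole may be part of the cause, since all its positions together were at -0.0951. It is argued against as the whole cause, since positions outside the window were at 0.12. The window also fell within the substrate's own UMIs, from 63.8% with vehicle to 57.9% with estradiol. Phases do not capture every shift in composition: cluster 2, which had the highest Abasic window, held 23.3% of vehicle and 2.44% of estradiol cells. Equal weight to each cluster left -0.14 (-0.20 to -0.08 within single clusters), so the shares of these clusters may be part of the cause but not the whole. Cells within a cluster differed between libraries too: G1 cells were 24.3% of cluster 1 with vehicle and 35.6% with estradiol. Equal weight to clusters therefore cannot exclude finer shifts in composition. Repair depth per cell may account for part or most of the Abasic difference. Over 5 bins of repair UMIs per cell the mean was -0.0658 (-0.14 to -0.00), with mean depths of 576 (vehicle) and 565 (estradiol) in the lowest bin and 1626 and 1769 in the highest. The bins are cut on the total that also scales the shares, and they moved other windows too. Uracil1 went from 0.06 to 0.25 and GU from 0.18 to 0.37. The bins therefore cannot show that depth was the cause. Clusters differ in depth too, so these tests overlap. With 1 library per treatment, a difference in library preparation and an effect of estradiol cannot be told apart.

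The uracil windows were higher in S than in G1 in both libraries, although with vehicle the wide interval of the Normal control (-0.01 to 0.60) also held the ratios of Uracil1, Uracil2 and GU. The vehicle intervals of CI (-0.26 to 0.37) and TI (-0.28 to 0.04), which also had few window UMIs, lay below those ratios. Repair depth per cell is argued against as the whole cause of the uracil rise in S. The mean S to G1 log2 ratio of Uracil1 over bins of repair UMIs was 0.44 with vehicle and 0.45 with estradiol. Single bins ran from 0.33 to 0.55 and from 0.30 to 0.56. These bins are cut on the total that also scales the shares, and they leave mRNA depth, on which phase calls depend, untouched. With phases called again on thinned cells the Uracil1 ratio was 0.34 with vehicle. Recovery of the whole substrate does not account for the rise. The highest ratio outside the window among Uracil1, Uracil2, Uracil3 and GU was 0.0589 (Uracil3, vehicle), against 0.88 in its window. A candidate explanation is the S-phase expression of UNG, a glycosylase that acts on uracil behind the replication fork; UNG is in the S-phase list, but its S to G1 log2 ratio was still 1.60 with vehicle and 1.30 with estradiol in phases called without it. Among S cells, those with an UNG UMI had a Uracil1 window share that differed by a log2 ratio of 0.0749 with vehicle (bootstrap interval over cells -0.05 to 0.21, 81 cells with and 692 without) and of -0.03 with estradiol (-0.15 to 0.11, 133 and 844). These intervals leave the question open, because few cells carry an UNG UMI, those that do were deeper (median all-gene UMIs 1326 against 1200 with vehicle and 1901 against 1439 with estradiol), and the transcript need not follow the enzyme within a phase.

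The share of S cells was higher with estradiol by 13.4 points. Thinned to 800 UMIs, the difference was 10.3 points, against 12.6 points for the same calls on the same cells before thinning, so most of it remained at equal depth. Without the 5% of cells with most panel UMIs it was 13.4 points, but leaving out so few cells could not have brought it under 8.79 points, so doublets remain open. Entry into S phase after estradiol and a difference between the cultures that estradiol did not make both remain open, untested with 1 library each, and free RNA, which phase calls also read, was not measured.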
